A study of Mus musculus with 22 samples.

How the data were processed

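Liver RNA of ICR mice aged 8 weeks had been pooled within 10 groups, per the labels, with 2 to 5 mice in each pool. The groups were sham-operated males and females, hypophysectomised (Hypox) males and females, whose pituitary had been removed, and Hypox mice of both sexes that received growth hormone (GH). GH-treated mice were killed 30 min after 1 injection, 90 min after 1 injection, or 30 min after the last of 2 injections given 4 h apart. Amplified RNA labelled with Alexa 555 (read in green) or Alexa 647 (read in red) was hybridised to 2-colour Agilent whole-genome arrays. The 22 arrays cover 11 comparisons of groups, each on 2 arrays of opposite dye. The arrays lay on 7 slides and were scanned on 4 days.

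The deposited scanner files hold, per the file headers, the mean signal intensity and the background median intensity of each spot in both channels, the scanner software's log10 ratio of its processed signals, and flags for control spots, outliers, saturation and signals well above background. The deposited value table holds log2 ratios, per the labels a normalized ratio of the 2 channels. Each of its 22 columns equalled the log2 form of 1 scanner file's log10 ratio within 0.0051 once the dyes were taken into account, with column medians between -0.02 and 0. For 6 columns that file carried the same label, and for 16 it was the other replicate of the same comparison. The numbering of the scanner files was used throughout, and every ratio was turned to the first named group over the second by the dyes in the labels.

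Signals of the 45018 spots on each array were background corrected with limma's normexp method (offset 50) and normalized by loess within each array, with control spots at weight 0. Control spots (1639 per array) and outlier flags (97 to 159 spots per array) were left out. Spots of the same probe were averaged, which left 41174 probes. Probes were named through the RefSeq table of mouse genes by accession without its version: 22064 probes matched a symbol and 19110 kept the name in the file. For each of 33767 gene names the probe with the highest mean intensity was kept, and named genes whose other probes went the opposite way are pointed out. Other probes that went the same way but by less are not always given. A gene was tested if it was well above background in at least 1 channel on both arrays of at least 1 comparison, which left 26191 genes, 13756 of them with a symbol. The median signal of an array lay between 294 and 376 in green and between 415 and 522 in red, over background medians of 245 to 290.5 and 316 to 346. A gene below background on every array of a group was given only as at least a stated fold, from the mean level of the bright group over the higher of the lowest reliable signal and its own level in the dim group.

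All log2 ratios were fitted with limma (version 3.58.1, R 4.3.3; lmFit and eBayes) in 1 model of 22 arrays with 11 coefficients, 1 per comparison, and a dye term for each probe. The model left 10 residual degrees of freedom and a prior of 2.50, and 2872 genes had a dye effect. Each P value was adjusted by the Benjamini-Hochberg method within its comparison. A gene was called at an adjusted p under 0.05 with both arrays going the same way. Differences between sexes or times were tested as contrasts of the same fit. The number of arrays limits the precision: each comparison rests on 2 arrays. Some pools recur on several arrays and were treated as independent, so the errors leave out that sharing. In males, the Hypox pools of 5 mice in the comparison after 2 injections hold mice in common, since the group had fewer mice than both pools together, and whether both female Hypox pools of that comparison are 1 pool is not known.

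The genes named in the text were chosen by a rule written before the data were examined. It takes the 10 largest rises and the 10 largest falls among called genes with a symbol that were well above background, and the 5 largest each way for differences. It adds up to 4 called members of each fixed gene list, and Cish, Socs2, Igf1, Bcl6, Cux2 and the sex chromosome genes in any comparison. Some genes that the rule takes are not reported here. A total of 28 lists of pathways and cell types were fixed before the data were examined, and camera tested each against all other genes with a preset correlation of 0.01. Counts of list members adjusted over the list alone are given where they differ from those over all genes. Every camera test was repeated with a correlation estimated from the data. That repeat also raised p values of lists whose estimated correlation was below 0.01. For the thyroid hormone targets in Hypox over sham males the estimate was -0.00195, and the camera adjusted p rose from 0.030 to 0.20. Correlation between genes alone thus does not account for the calls that the repeat lost. A list of 29 skeletal muscle genes was written after its first 11 members had been seen to stand apart.

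The test was checked on simulated arrays with independent noise and no shared pools, built on the spread of 26191 genes. For sham males against females, 73.1% of genes changed 1.5-fold, 89.6% of those changed 2-fold and 98.5% of those changed 4-fold were called, with 9 false calls among 183. For GH at 30 min the shares were 76.1%, 91.0% and 98.5% in males (8 false calls among 185), and 71.6%, 94.0% and 98.5% in females (6 among 182).

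Alternatives fixed before the data were examined were the scanner's log ratios, the value table, median centring in place of loess, no filter on dim probes, no dye term, a model of group levels over the whole loop of arrays, paths around the loop, slide and scan day as random blocks, a replicate block, each comparison fitted alone, each array left out in turn, and an estimated correlation in camera. Terms for slide and scan day were added later: a dye balance for each slide, which leaves 4 of 17 results estimable, a dye balance for each scan day, and a shift between the slides of each pair that hold the same comparisons. Also added later were fits without 5 doubted arrays, without the arrays of sham mice, counts without genes that follow muscle or pancreas, and the Y-linked genes under other scalings. Shared sham pools were simulated in 20 runs of 26163 unchanged genes, and in 20 runs with fitted effects, shrunk by their share of error, of which those of hypophysectomy were shuffled over genes of like intensity. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Genes without a symbol were counted but not named, and positions in the genome were not analysed here.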

Results

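Gene expression was measured in the livers of male and female mice that were sham-operated, had lost the pituitary (Hypox), or had lost it and received growth hormone (GH), which the pituitary releases. The 22 arrays compared pools of liver RNA in 11 pairings of 10 groups, each pairing on 2 arrays of opposite dye, with 2 to 5 mice in a pool. Of 33767 gene names, 26191 were tested. Between 57.1% and 77.7% of the spots of a channel were well above background, with the lowest share in the red channel of replicate 2 of female Hypox against sham. Each log2 ratio below is the first named group over the second, as the mean of 2 arrays ± SE, unless said otherwise. The SE comes from the limma fit to all 22 arrays. It is therefore about the same for a gene in each comparison and is not the spread between the 2 arrays shown. The Y-linked genes Eif2s3y, Ddx3y, Kdm5d and Uty followed the sexes in the labels on 22 of 22 arrays. The positions of the genes in the genome were not used here.

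**Figure D1:**
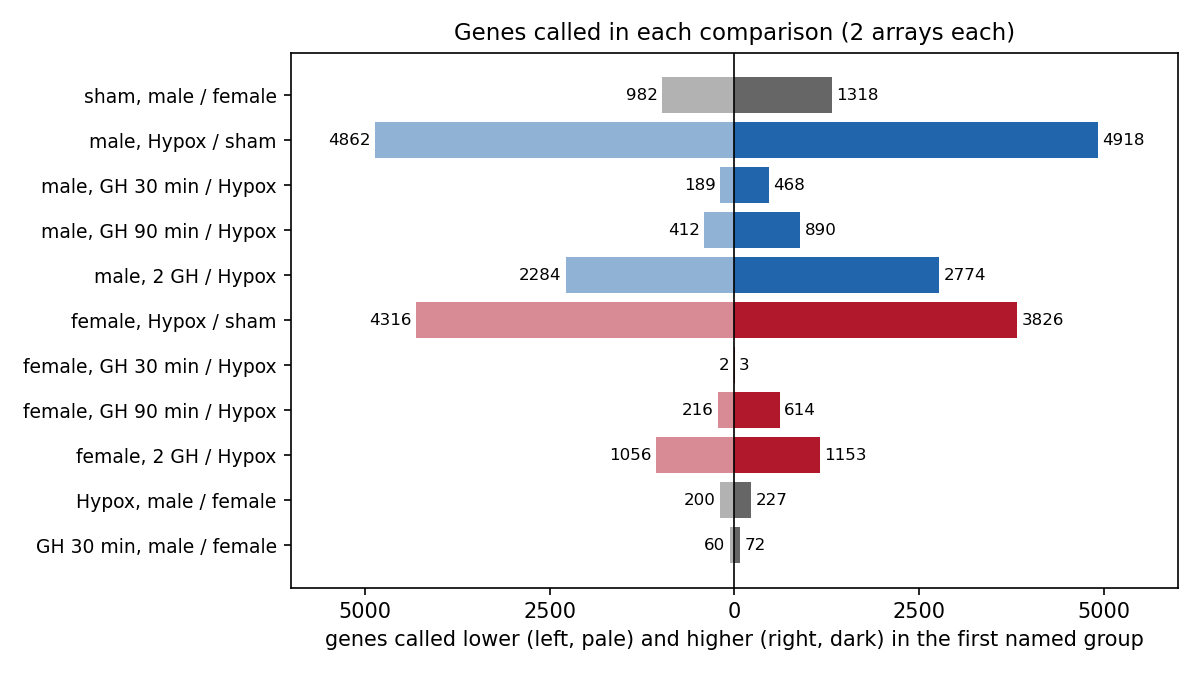
Number of genes that passed the limma test in each of the 11 comparisons, with higher genes above 0 and lower genes below. The bars for hypophysectomy are 9780 genes in males and 8142 in females, and those for GH run from 5 (30 min, females) to 5058 (2 injections, males).

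The comparison of sham males with sham females asked how the intact liver differs between the sexes. Higher in males were these members of a fixed list of male-biased liver genes: Cyp4a12a, which hydroxylates fatty acids (4.55 ± 0.25, adjusted p = 1.3e-07), Elovl3, which lengthens fatty acid chains (3.70 ± 0.12, adjusted p = 1.0e-09), and Hsd3b5, a steroid dehydrogenase (2.49). Several female-biased genes were lower in males: the sulfotransferase Sult3a1 (-8.40 ± 0.67, adjusted p = 3.7e-06), the hydroxyacid oxidase Hao2 (-6.36 ± 0.24, adjusted p = 4.7e-09) and the cytochrome P450 gene Cyp2b9 (-4.06 ± 0.12, adjusted p = 9.8e-10). The acetyltransferase genes Nat8f5 (5.28) and Nat8 (3.86), the trefoil factor Tff3 (3.69) and the oxidase Nox4 (3.19) were higher in males. The female-biased sulfotransferase Sult2a2 (-5.97) and the anion carriers Slc22a26 (-5.24) and Slc22a29 (-4.48) were lower. The transcriptional repressor Bcl6 was higher in males (1.89 ± 0.28, adjusted p = 7.0e-04), and the transcription factors Cux2 (-1.97 ± 0.14, adjusted p = 9.2e-07), Tox (-2.47), Trim24 (-1.99) and Esr1, the oestrogen receptor (-1.30), were lower. The X-linked Xist, which silences an X chromosome in females, was lower in males (-2.76), and Eif2s3y was higher (6.68).

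Further lists differed between the sham sexes as well. Of 6 heat shock genes, 5 were higher in males, such as the chaperones Hspa1a (2.59) and Hspb1 (2.21; camera adjusted p = 3.7e-06, or 0.099 with an estimated correlation). Some endoplasmic reticulum (ER) stress genes were higher too (3 of 12, and 7 adjusted over the list alone; adjusted p = 7.8e-05, or 0.099 with an estimated correlation), with the asparagine synthetase Asns at 2.06. Some genes controlled by PPARα, the receptor that turns on fatty acid oxidation, were lower in males (8 of 24, and 10 adjusted over the list alone; adjusted p = 2.9e-05, or 0.28 with an estimated correlation), with Cyp4a14 at -3.37. The metallothionein genes Mt1 (-2.57) and Mt2 (-2.90) and the chaperone Fkbp5 (-0.99), from the list of glucocorticoid targets, were lower (adjusted p = 0.0078, or 0.099 with an estimated correlation). The Kupffer cell marker Clec4f (-0.60) and the macrophage receptor Vsig4 (-0.61) were lower as well (macrophage list adjusted p = 0.0014, or 0.51 with an estimated correlation).

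limma called 2300 genes between sham males and females, 1318 higher and 982 lower in males, 882 of them by at least 1.5-fold. The list of 16 male-biased genes had 15 higher, and 16 adjusted over the list alone (median log2 ratio 2.26; adjusted p = 3.6e-28, or 7.0e-04 with an estimated correlation). The list of 26 female-biased genes had 25 lower, and 26 adjusted over the list alone (median -2.41; adjusted p = 6.3e-46, or 7.0e-04 with an estimated correlation). Of 25 liver transcription factors, 2 were higher and 7 lower (adjusted p = 0.0078, or 0.099 with an estimated correlation). Across genes, the ratios of both arrays correlated at r = 0.691, where genes are not independent replicates. The count was 971 without replicate 1, 929 without replicate 2 and 633 when both arrays were fitted alone, 425 with median centring and 4115 in the loop model. Cish had -1.33 ± 0.68 (adjusted p = 0.29, arrays 0.51 and -3.17), and the median of 25 skeletal muscle genes was 1.46 and 2.55 on the 2 arrays.

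Removal of the pituitary in males asked which genes depend on pituitary hormones there. The major urinary protein genes Mup1 and Mup5 fell, with Mup1 at -7.04 ± 0.57, adjusted p = 1.5e-06 and Mup5 at -5.53. The male-biased Elovl3 (-3.96 ± 0.12, adjusted p = 3.6e-10), Hsd3b5 (-3.55), Cyp7b1, which hydroxylates oxysterols (-3.65), and Nat8f5 (-4.37) fell too. Several female-biased genes rose: Hao2 (5.68 ± 0.24, adjusted p = 5.2e-09), Cyp2b9 (3.71 ± 0.12, adjusted p = 9.0e-10), Cyp2b13 (3.20) and Atp6v0d2, a proton pump subunit (3.71). Igf1, the growth factor induced by GH, fell (-2.46 ± 0.16, adjusted p = 2.8e-07), as did Igfals, which carries it in blood (-1.90), the GH signal inhibitors Socs2 (-2.55 ± 0.39, adjusted p = 2.4e-04) and Cish (-2.41 ± 0.68, adjusted p = 0.014), and Bcl6 (-1.53 ± 0.28, adjusted p = 8.2e-04). Some genes that answer to thyroid hormone fell: Dio1, which activates the hormone (-4.63 ± 0.34, adjusted p = 6.7e-07), Gpd2 (-1.99) and Klf9 (-1.71), while Serpina7, which carries the hormone in blood, rose (3.32). The organic anion transporter Slco1a1 (-4.47) and the protease inhibitor Serpina3k (-4.42) fell. The keratin Krt23 (3.95) and the transporter Slco1a4 (3.58) rose.

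The chaperone genes fell in Hypox males: Hsph1 (-3.29 ± 0.19, adjusted p = 8.4e-08) and Hsp90aa1 (-2.86) were among 6 of 6 heat shock genes called lower (adjusted p = 2.6e-06, or 0.20 with an estimated correlation). Of 12 ER stress genes 8 fell and 1 rose, with Sdf2l1 at -2.63 (adjusted p = 0.0026, or 0.23 with an estimated correlation). Of 15 bile acid genes 9 fell and 1 rose, Cyp27a1 at -1.77 (adjusted p = 0.0029, or 0.27 with an estimated correlation). Of 21 cholesterol synthesis genes 9 fell and 1 rose, Nsdhl at -1.54 (1 higher and 10 lower adjusted over the list alone, adjusted p = 0.043, or 0.89 with an estimated correlation). The PPARα targets went both ways, 9 of 24 higher and 10 lower, and camera did not call the list (9 higher and 11 lower adjusted over the list alone, adjusted p = 0.50, or 0.89 with an estimated correlation). Of these targets Cyp4a14 (3.70) and Cd36, a fatty acid carrier (1.89), rose, while Angptl4 (-3.08) and the lipid droplet gene Plin2 (-1.69) fell. The B cell markers Cd79b (1.81) and Ms4a1 (1.83) rose, with 7 of 10 lymphocyte genes called higher (adjusted p = 0.0069, or 0.45 with an estimated correlation).

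limma called 9780 genes in Hypox against sham males, 4918 higher and 4862 lower, 3446 of them by at least 1.5-fold. All 16 genes of the male-biased list fell (median -2.81; adjusted p = 1.2e-13, or 0.033 with an estimated correlation). Of 26 female-biased genes 14 rose and 2 fell, the cytokine receptor Lifr at -2.84 (median 0.93; adjusted p = 6.4e-05, or 0.23 with an estimated correlation). Of 13 GH and STAT5 targets 7 fell, Bcl6 among them, and 7 adjusted over the list alone (adjusted p = 0.0054, or 0.40 with an estimated correlation). Of 8 thyroid hormone targets 5 fell, 6 adjusted over the list alone, and 2 rose (adjusted p = 0.030, or 0.20 with an estimated correlation). The ratios of both arrays correlated across genes at r = 0.84. The count was 5051 without replicate 1, 6513 without replicate 2, 2998 with median centring and 5708 with both arrays fitted alone. Cish was at -4.21 and -0.61 on the 2 arrays, and the muscle genes had medians of -1.64 and -2.70.

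Removal of the pituitary in females asked the same question. Several female-biased genes fell: Sult3a1 (-8.70 ± 0.67, adjusted p = 2.2e-06), Lifr (-3.12), Cyp2c40 (-2.87) and Cux2 (-2.19 ± 0.14, adjusted p = 3.5e-07). The male-biased Cyp4a12a rose (3.92 ± 0.25, adjusted p = 4.9e-07), while Hsd3b5 (-3.16) and Elovl3 (-1.49) fell. Several targets of GH fell, with Cish at -4.14 ± 0.68, adjusted p = 6.2e-04, Socs2 at -3.81 ± 0.39, adjusted p = 2.1e-05, Igf1 at -3.25 ± 0.16, adjusted p = 5.9e-08 and Igfals at -2.49. The cholesterol synthesis gene Nsdhl (-1.89) fell, and so did the lipogenic genes Thrsp (-2.08) and Pnpla3 (-1.69). Lpl, the lipase that clears blood fats (4.28 ± 0.18, adjusted p = 1.7e-08), Serpina7 (4.18), the calcium-binding S100g (3.98) and the RNA-binding Igf2bp3 (3.19) rose. Mup1 (-6.30), Dio1 (-4.50), Serpina3k (-4.04) and Esr1 (-3.13) fell.

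limma called 8142 genes in Hypox against sham females, 3826 higher and 4316 lower, 2666 of them by at least 1.5-fold. Of 26 female-biased genes 17 fell (median -1.36; adjusted p = 3.3e-08, or 0.19 with an estimated correlation). Of 16 male-biased genes 8 fell and 2 rose (3 higher and 8 lower adjusted over the list alone, adjusted p = 0.027, or 0.42 with an estimated correlation). Of 21 cholesterol genes 15 fell, 16 adjusted over the list alone, and 1 rose (adjusted p = 6.7e-06, or 0.40 with an estimated correlation). Of 13 GH and STAT5 targets 6 fell and 0 rose, and adjusted over the list alone 7 fell and 2 rose (adjusted p = 0.0029, or 0.33 with an estimated correlation). Of 14 lipogenic genes 7 fell and 1 rose (3 higher and 8 lower adjusted over the list alone, adjusted p = 0.043, or 0.19 with an estimated correlation). Of 8 thyroid hormone targets 5 fell and 2 rose (adjusted p = 0.023, or 0.19 with an estimated correlation). Of 25 liver transcription factors 11 fell and 1 rose (3 higher and 11 lower adjusted over the list alone, adjusted p = 0.013, or 0.19 with an estimated correlation). Of 6 heat shock genes 4 fell (adjusted p = 0.0058, or 0.36 with an estimated correlation). Both arrays correlated across genes at r = 0.785. The count was 4983 without replicate 1 and 3401 without replicate 2, whose red channel had the fewest spots above background, 1899 with median centring and 3503 with both arrays fitted alone.

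Hypophysectomy moved many genes the same way in both sexes: 2672 genes rose in males and in females (718 if calls were independent) and 2619 fell (801). Sex-biased genes were among those that differed. Hao2 rose in males and fell in females (-0.85), a difference of 6.53 ± 0.34, adjusted p = 6.1e-07. Cyp4a12a fell in males (-1.71) and rose in females, a difference of -5.62 ± 0.36, adjusted p = 1.6e-06. The test of the difference called 1763 genes, 843 with a higher ratio in males and 920 with a lower one. Among them were 22 of 26 female-biased genes with a higher ratio in males (25 higher and 0 lower adjusted over the list alone, adjusted p = 8.7e-36, or 0.0021 with an estimated correlation). A lower ratio in males was called for 10 of 16 male-biased genes (0 higher and 13 lower adjusted over the list alone, adjusted p = 5.9e-17, or 0.0080 with an estimated correlation). The sham groups enter both this difference and sham males over females, so these list tests are not separate evidence of the sex bias in sham mice. Bcl6 (-2.28 ± 0.39, adjusted p = 0.0046) and Cux2 (2.33 ± 0.19, adjusted p = 1.5e-05) differed too. Leaving out 1 array gave 575 to 861 genes, median centring gave 147 and the loop model 5804.

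Hypox males were set against Hypox females to ask which sex differences remain without a pituitary. Apart from the Y-linked genes and Xist (-2.39), Nat8 (2.19 ± 0.39, adjusted p = 0.018) and Nat8f5 (2.17 ± 0.43, adjusted p = 0.030) stayed higher in males, and Sult2a2 (-3.61 ± 0.46, adjusted p = 0.0035) stayed lower. Elovl3 (0.71) and Cyp7b1 (0.82) were higher in males. The cell cycle kinase Wee1 (1.35 ± 0.28, adjusted p = 0.035) was higher, and Igf2bp3 (-1.83 ± 0.29, adjusted p = 0.010), Prom1, a stem cell surface protein (-1.47 ± 0.17, adjusted p = 0.0018), the synaptic Lrrc4 (-1.62 ± 0.19, adjusted p = 0.0022) and the lipid transporter Mfsd2a (-1.70) were lower. The circadian genes Cry2 (0.63, with 0.15 for its other probe) and Hlf (0.88) were higher in males. The 1318 genes called higher in sham males had a median of 0.0160 in Hypox males over females, and the 982 called higher in sham females one of -0.0374. Their medians in the sham mice they were chosen in (0.458 and -0.524) are raised in size by that choice.

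limma called 427 genes between Hypox males and females, 227 higher and 200 lower in males, 142 of them by at least 1.5-fold. Of the 427, 38 were also higher and 52 also lower in sham males (11.4 and 7.50 if independent). In the opposite direction, 14 genes higher in sham males were lower in Hypox males, and 17 lower in sham males were higher. The male-biased list had 2 of 16 higher, and 4 adjusted over the list alone (adjusted p = 0.0031, or 0.50 with an estimated correlation). The female-biased list had 3 lower and 1 higher, against 11 and 3 adjusted over the list alone (adjusted p = 0.0031, or 0.50 with an estimated correlation). The clock list had 2 of 17 higher (9 higher and 3 lower adjusted over the list alone, adjusted p = 0.030, or 0.50 with an estimated correlation). The cholesterol list had 0 called over all genes and 3 higher adjusted over the list alone (adjusted p = 3.1e-05, or 0.59 with an estimated correlation). Both arrays correlated across genes at r = 0.256. The count was 24 without replicate 1, 66 without replicate 2 and 8 with both arrays fitted alone, and 2616 in the loop model.

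**Figure D2:**
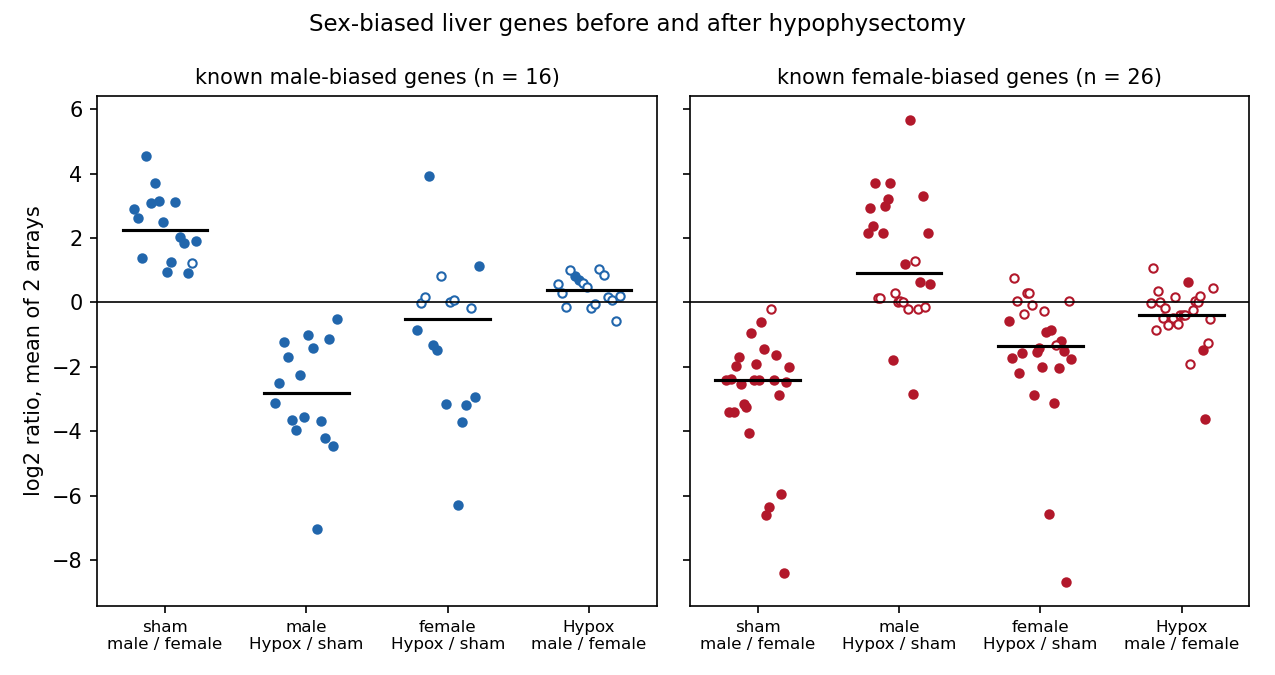
log2 ratios of the 16 genes of the male-biased list and the 26 of the female-biased list in 4 comparisons, each point a gene (mean of 2 arrays), filled where the limma test called it, with a line at the median. The medians of the male-biased genes are 2.26 in sham males over females and -2.81 in Hypox over sham males, and those of the female-biased genes -2.41 and 0.93.

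The comparisons 30 min after 1 GH injection asked which genes answer first. Socs2 rose in Hypox males (2.22 ± 0.39, adjusted p = 0.020) and in Hypox females (2.97 ± 0.39, adjusted p = 0.027). In males the pleckstrin-like Phlda1 (3.02 ± 0.50, adjusted p = 0.017), the stress response gene Gadd45g (2.47 ± 0.59, adjusted p = 0.047) and the histone demethylase Kdm6b (1.23 ± 0.22, adjusted p = 0.021) also rose. The chitinase-like Chil4 (-3.27 ± 0.70, adjusted p = 0.033), the protease inhibitor Spink4 (-3.12 ± 0.74, adjusted p = 0.048) and the trefoil factor Tff2 (-2.48 ± 0.58, adjusted p = 0.043), genes of mucous surfaces, fell in males. In females Spc24, a kinetochore gene, fell (-0.94 ± 0.10, adjusted p = 0.0062). Cish, which is induced by STAT5, had 2.19 ± 0.68 in males (arrays 2.52 and 1.85; adjusted p = 0.10) and 2.88 ± 0.68 in females (arrays 2.95 and 2.80; adjusted p = 0.25), and did not pass. Without the arrays of sham mice in the fit the adjusted p of Cish was 0.0025 in males and 0.00028 in females. That fit was chosen after the results were seen. It leaves out arrays on which Cish varied between replicates, 0.51 and -3.17 in sham males over females and -4.21 and -0.61 in Hypox over sham males. It is therefore not a separate test of Cish. The lipogenic genes had lower ratios as a list in females (median -0.28, adjusted p = 1.9e-07, or 0.0030 with an estimated correlation), with 0 called over all genes and 4 lower adjusted over the list alone. They had lower ratios in males too (median -0.33, adjusted p = 0.0035, or 0.062 with an estimated correlation), again with 0 called and 4 lower adjusted over the list alone. In females Fasn, the fatty acid synthase, had -0.93 ± 0.16 (adjusted p = 0.10).

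limma called 657 genes in males, 468 higher and 189 lower, 266 by at least 1.5-fold. In females it called 5, 3 higher and 2 lower, where 1976 genes had an unadjusted p under 0.05, and 3 of the 5 have no symbol. The counts do not show a difference between the sexes: the test of the difference called 2 genes, Spc24 (1.102 ± 0.141) and Tmpo, a nuclear envelope gene (-0.89 ± 0.09), where 3069 had an unadjusted p under 0.05. The GH and STAT5 list was higher in females (1 of 13 called, 4 adjusted over the list alone; adjusted p = 3.3e-04, or 0.57 with an estimated correlation). So was the list of lymphocyte genes with 0 called (adjusted p = 0.0011, or 0.61 with an estimated correlation). Both arrays correlated across genes at r = 0.168 in males and 0.295 in females. In males the count was 147 without replicate 1, whose muscle genes had a median of 3.02, and 13 without replicate 2, 13 with median centring, 0 with both arrays alone and 344 with the scanner's log ratios (150 higher and 194 lower). In females it was 0 without either array, and 163 in the loop model.

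Both sexes were compared directly 30 min after GH to ask how they differ under treatment. The Y-linked genes were higher in males, and Xist was at least 5.3-fold lower, below background there. Cyp4a12a (1.77 ± 0.25, adjusted p = 0.0086), Wee1 (1.43) and the lipogenic Thrsp (1.19 ± 0.23, adjusted p = 0.040) were higher in males. The other probe of Cyp4a12a had only 0.096. Sult2a2 (-4.28 ± 0.46, adjusted p = 8.5e-04), Lrrc4 (-2.03 ± 0.19, adjusted p = 3.3e-04) and Prom1 (-1.29) were lower in males. limma called 132 genes, 72 higher and 60 lower in males, 76 by at least 1.5-fold. Of these, 27 were also higher and 37 also lower in Hypox males over females (0.624 and 0.458 if independent). The male-biased list (1 of 16 higher; 3 higher and 0 lower adjusted over the list alone, adjusted p = 8.0e-04, or 0.28 with an estimated correlation) and the female-biased list (2 of 26 lower; 0 higher and 8 lower adjusted over the list alone, adjusted p = 1.4e-07, or 0.15 with an estimated correlation) went the way they do in sham mice. PPARα targets had lower ratios with 0 called (0 higher and 1 lower adjusted over the list alone, adjusted p = 2.4e-06, or 0.28 with an estimated correlation). Interferon response genes had higher ones with 0 called (median 0.77; adjusted p = 5.2e-06, or 0.67 with an estimated correlation), and so did clock genes (1 called; 8 higher and 3 lower adjusted over the list alone, adjusted p = 0.0017, or 0.27 with an estimated correlation). Both arrays correlated across genes at r = 0.00672. The count was 23 without replicate 1, whose muscle genes had a median of 2.97, 278 without replicate 2, and 0 with both arrays alone.

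By 90 min after GH, Cish had risen in males (4.17 ± 0.68, adjusted p = 0.0040) and females (4.17 ± 0.68, adjusted p = 0.0065), as had Socs2 (3.33 and 3.89) and Phlda1 (4.15 and 3.36). Further rises in both were the growth regulator Myc (2.62 ± 0.53, adjusted p = 0.014 in males, 2.97 ± 0.53, adjusted p = 0.011 in females) and the nerve-related Nrep (2.97 and 2.59). The transcription factor Foxa1 rose in both sexes (1.46 and 1.37), as did Xbp1, a regulator of secretion (1.37 and 0.90), and Il1rn, an inhibitor of interleukin 1 (1.35 and 1.31). In males Socs1 (2.20 ± 0.46, adjusted p = 0.016) and Serpina3k (2.35 ± 0.29, adjusted p = 7.3e-04) rose. G6pc, which releases glucose (-2.24 ± 0.41, adjusted p = 0.0074), Depp1, induced by fasting (-2.11 ± 0.37, adjusted p = 0.0058), and Snai2 (-1.57) fell. Ppp1r3b, which directs glycogen synthesis, fell in both sexes (-1.38 and -1.18). In females the lipase inhibitor G0s2 (-1.86 ± 0.28, adjusted p = 0.0041), the lipogenic Fasn (-1.03 ± 0.16, adjusted p = 0.0057) and Thrsp (-0.99 ± 0.23, adjusted p = 0.034) fell, and Igf1 rose (0.73 ± 0.16, adjusted p = 0.032).

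limma called 1302 genes in males at 90 min, 890 higher and 412 lower, 510 by at least 1.5-fold. In females it called 830, 614 higher and 216 lower, 291 by at least 1.5-fold. Of these 270 rose in both sexes (20.9 if independent) and 53 fell in both (3.40). The test of the difference called 2 genes, Zfp790 (0.74 ± 0.08) and the receptor Fgfr3 (0.71 ± 0.08), where 2640 genes had an unadjusted p under 0.05. Of 13 GH and STAT5 targets 5 rose in males (7 higher and 1 lower adjusted over the list alone; adjusted p = 0.0019, or 1.0 with an estimated correlation) and 4 in females (6 adjusted over the list alone; adjusted p = 0.0031, or 0.54 with an estimated correlation). Of 23 immediate-early genes 3 rose in males (4 higher and 1 lower adjusted over the list alone, adjusted p = 0.018, or 1.0 with an estimated correlation), and 4 rose and 2 fell in females (8 higher and 2 lower adjusted over the list alone, adjusted p = 0.0071, or 0.65 with an estimated correlation). Both arrays correlated across genes at r = 0.516 in males and 0.495 in females. In males the count was 146 without replicate 1 (muscle median 2.18), 329 without replicate 2, and 120 with median centring. In females it was 501 without replicate 1, 88 without replicate 2 and 5 with both arrays alone, with 531 higher and 427 lower by the scanner's log ratios. With median centring it was 1058 (846 higher and 212 lower), where the median of all genes moved to 0.24 and 140 of the genes called here had the other sign.

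Lipogenic genes were lower as a list in females at 90 min (2 of 14 called, 5 adjusted over the list alone; median -0.29; adjusted p = 5.9e-05, or 0.014 with an estimated correlation). With median centring that median was 0.11, where the median of all genes was 0.24. In males cholesterol synthesis genes had lower ratios with 0 called (median -0.37; adjusted p = 0.018, or 1.0 with an estimated correlation). The gluconeogenic list had 1 lower (0 higher and 3 lower adjusted over the list alone, adjusted p = 0.032, or 1.0 with an estimated correlation), and the acute-phase list had 2 higher, among them the fibrinogen gene Fgg at 0.86 (3 higher and 0 lower adjusted over the list alone, adjusted p = 0.032, or 1.0 with an estimated correlation). In females endothelial markers (1 called higher, 5 adjusted over the list alone; adjusted p = 0.0032, or 0.54 with an estimated correlation) and macrophage markers (0 called; adjusted p = 0.020, or 0.65 with an estimated correlation) had higher ratios as lists.

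From 30 to 90 min after GH, Nrep rose in males (2.65 ± 0.33, adjusted p = 0.0037) and females (2.66 ± 0.33, adjusted p = 0.010), as did Sybu, a carrier of vesicles along microtubules (1.89 and 1.47), whose probes differed in direction in males. In males Serpina3k (2.88) and the ketone-using Aacs (2.67) rose, and Lars2 (-2.62), Depp1 (-2.46) and the filament gene Synm (-1.60) fell. In females the Wnt receptor Fzd7 (1.47) and the esterase Nceh1 (1.45) rose. The test of the difference called 648 genes in males (367 higher, 281 lower) and 41 in females (38 higher, 3 lower). Leaving out 1 array gave 25 to 450 genes in males and 0 to 41 in females, and median centring gave 8 and 0.

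**Figure D3:**
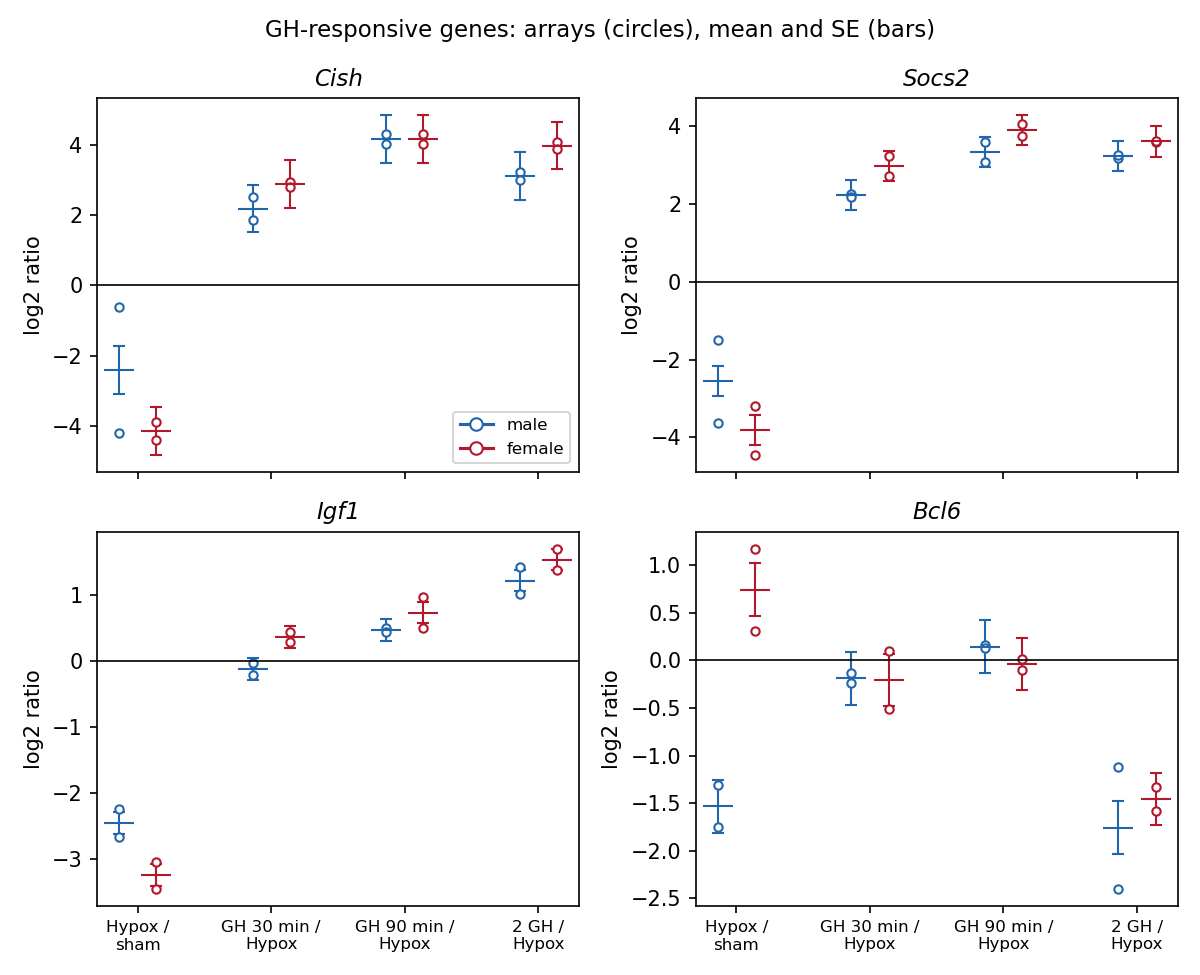
log2 ratios of Cish, Socs2, Igf1 and Bcl6 on each array (points) with the mean and SE of 2 arrays, males in blue and females in red, for hypophysectomy and 3 GH treatments. Cish reaches 4.17 in both sexes at 90 min, and Igf1 is at -2.46 in males and -3.25 in females after hypophysectomy.

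A second GH injection was given 4 h after the first, with the mice killed 30 min later, to ask what both injections do together. No group was killed as long after a single injection. Effects of the second injection therefore cannot be told apart from later effects of the first. Igf1 rose in males (1.22 ± 0.16, adjusted p = 2.6e-04) and females (1.53 ± 0.16, adjusted p = 3.7e-04), as did Igfals (1.68 and 1.92), Socs2 (3.22 and 3.60), Cish (3.11 and 3.98), Serpina3k (3.25 and 2.27) and Nrep (2.95 and 2.64). Bcl6 fell in males (-1.76 ± 0.28, adjusted p = 7.2e-04) and females (-1.45 ± 0.28, adjusted p = 0.0090). The ER chaperone genes Hspa5 (1.48 ± 0.20, adjusted p = 3.0e-04) and Dnajb9 (1.39 ± 0.15, adjusted p = 6.9e-05) rose in males, and Dnajb9 (0.70) and Xbp1 (0.69) in females. The cholesterol synthesis gene Mvd rose in males (1.09) and females (0.96). In males Krt23 fell (-2.48 ± 0.26, adjusted p = 4.4e-05), as did the fatty acid oxidation gene Cpt1a (-0.51) and the glucose carrier Slc2a2 (-0.80). In females Aacs (2.02 ± 0.12, adjusted p = 8.0e-06) and Ddc, which makes biogenic amines (1.98), rose.

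limma called 5058 genes in males after 2 injections, 2774 higher and 2284 lower, 1433 by at least 1.5-fold. In females it called 2209, 1153 higher and 1056 lower, 683 by at least 1.5-fold. Of these 848 rose in both sexes (122 if independent) and 334 fell in both (92.1). Of 12 ER stress genes 9 rose in males (9 higher and 1 lower adjusted over the list alone, adjusted p = 3.2e-04, or 0.66 with an estimated correlation) and 2 in females (adjusted p = 0.046, or 0.89 with an estimated correlation). Of 21 cholesterol genes 6 rose in males (7 adjusted over the list alone; adjusted p = 0.0054, or 0.79 with an estimated correlation) and 3 in females (14 adjusted over the list alone; adjusted p = 1.7e-06, or 0.89 with an estimated correlation). Of 13 GH and STAT5 targets 4 rose and 1 fell in females (5 higher and 1 lower adjusted over the list alone, adjusted p = 0.0067, or 0.89 with an estimated correlation), with 5 higher and 2 lower in males (camera adjusted p = 0.21). Bcl6 belongs to this list, and was the gene called lower in females and among those called lower in males. Members thus moved both ways after GH, which a camera test of a shift in a single direction can understate. In males 7 of 24 PPARα targets (adjusted p = 0.013, or 0.79 with an estimated correlation) and 2 of 11 gluconeogenic genes (adjusted p = 0.0066, or 0.79 with an estimated correlation) fell. In females 3 of 23 immediate-early genes fell (1 higher and 5 lower adjusted over the list alone, adjusted p = 0.014, or 0.94 with an estimated correlation). Both arrays correlated across genes at r = 0.534 in males, where the Hypox pools share mice, and 0.743 in females. In males the count was 1619 without replicate 1, 2867 without replicate 2, 458 with median centring and 1049 with both arrays alone. In females it was 206 without replicate 1, 104 without replicate 2 and 81 with median centring.

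Genes of skeletal muscle were the largest falls in females after 2 injections: titin, Ttn (-4.92 ± 1.28, adjusted p = 0.034), the myosin genes Myh4 (-4.83 ± 1.21, adjusted p = 0.029), Myh7 (-3.90) and Myl1 (-4.39), the troponin Tnnt3 (-3.92) and the muscle creatine kinase Ckmt2 (-4.29). In males genes of the exocrine pancreas were among the largest rises, with the lipase Pnlip at 0.92 and 4.57, the elastase Cela3b at 0.59 and 4.75 and Reg1 at 0.44 and 5.45 on the 2 arrays (pancreas list 6 of 7 higher; adjusted p = 3.0e-04, or 0.79 with an estimated correlation). Of 299 genes that follow muscle or pancreas over the arrays, 205 were among the genes called lower in females after 2 injections and 32 among those called higher in males. The list of stellate cell genes was lower in females (2 called; 0 higher and 5 lower adjusted over the list alone, adjusted p = 0.0011, or 0.89 with an estimated correlation), 1 of them Des, which muscle also expresses (-1.26). The test of the difference between the sexes called 518 genes, 291 with a higher ratio in males and 227 with a lower one, and leaving out 1 array gave 5 to 131. In it the muscle calcium buffer Pvalb (4.03 ± 0.84) was higher and Krt23 (-1.75 ± 0.36) lower in males.

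**Figure D4:**
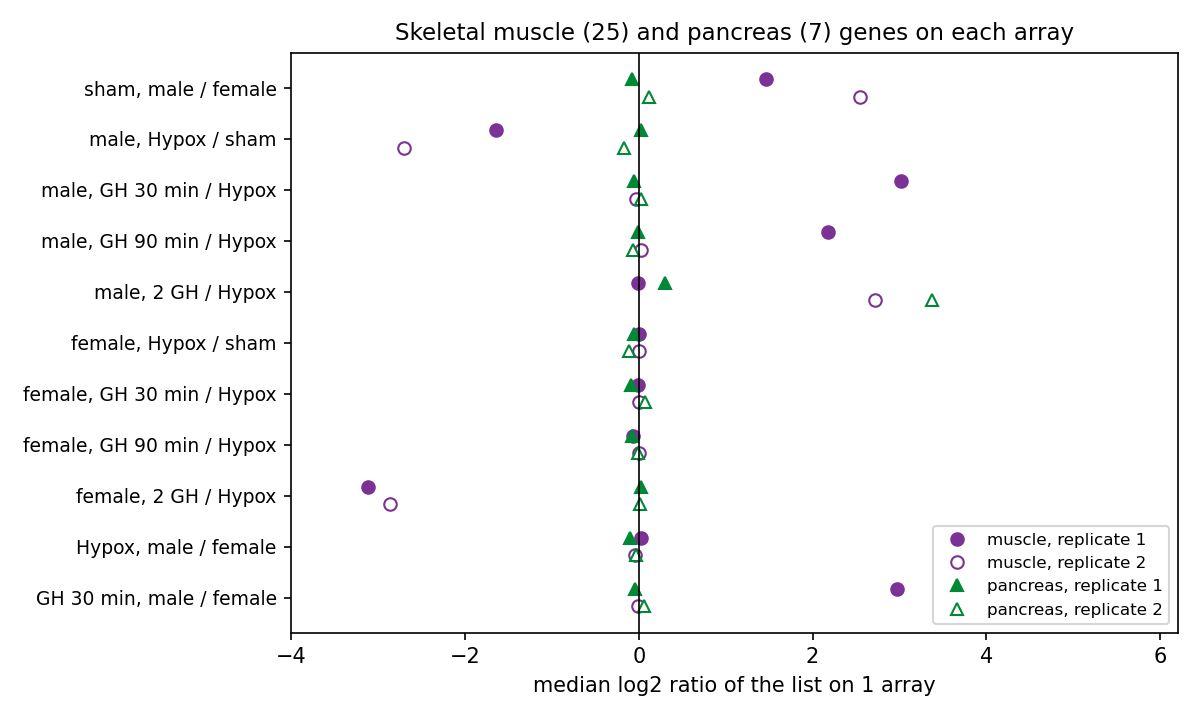
Median log2 ratio of 25 skeletal muscle genes and of 7 pancreas genes on each of the 22 arrays, by comparison and replicate. The muscle median lies at -3.11 and -2.86 in females after 2 injections and at 3.02 and -0.03 in males 30 min after GH, and the pancreas median at 3.38 on 1 array.

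Of 308 pairs of a list and a comparison, camera called 79 with the preset correlation and 8 with an estimated one. These 8 were the male-biased, female-biased and sex chromosome lists between sham males and females, the male-biased list in Hypox males, the lipogenic list in females 30 and 90 min after GH, and the sex chromosome list in both other comparisons of males with females (adjusted p = 2.1e-04 with an estimated correlation in Hypox mice). The arrays lay on 7 slides scanned on 4 days. A dye balance fitted for each slide left 4 results estimable: 5570 genes were called in males after 2 injections, 401 between both sexes 30 min after GH, and 1116 in males and 37 in females from 30 to 90 min. A dye balance for each scan day left all 17 counts estimable, with 2668 genes between sham males and females, 10579 in Hypox males, 8735 in Hypox females and 1361 in males at 30 min.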

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

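The tests of the muscle, pancreas and GH pulse explanations in this part were chosen only after the results were seen, except the test of an acute-phase state. Effects that differ between males and females, or between 30 and 90 min after GH, are given first, each from a test of the difference itself.

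After hypophysectomy several enzymes and transporters that are female-biased in intact mice had higher ratios in males than in females. The differences in log2 ratio were 8.55 for the sulfotransferase Sult3a1, 6.53 for the oxidase Hao2, 5.70 for the anion carrier Slc22a26 and 4.81 for Sult2a2, whose probes differed in direction. Some male-biased genes had lower ratios in males: -5.62 for Cyp4a12a, -3.77 for Nat8f5 and -3.64 for Tff3, with -3.19 for the ferritin receptor Scara5 and -3.06 for the glutathione transferase Gstp1. The regulators Bcl6 (-2.28) and Cux2 (2.33) differed in opposite directions. The test called 1763 genes. The difference uses other sham pools for each sex, but both sham groups are also those of sham males over females, taken with the opposite sign. Hao2 had -6.36 in that comparison. The difference is therefore not separate evidence of the sex bias in sham mice.

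After 2 GH injections 518 genes differed between the sexes. Ratios were higher in males for genes that muscle expresses, Pvalb (4.03), the calcium pump regulator Pln (3.12), Asb14 (2.80) and Dusp26 (2.32). They were lower in males for the lipase Gdpd3 (-4.23), Lrtm1 (-2.90), the signal regulator Rgs8 (-1.95), Lrit1 (-1.87) and the keratin Krt23 (-1.75). At 30 min 2 genes differed, Spc24 (1.102) and Tmpo (-0.89), and at 90 min 2, Zfp790 (0.74) and Fgfr3 (0.71).

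From 30 to 90 min after GH 648 genes differed in males and 41 in females. In males the rises included Serpina3k (2.88), Aacs (2.67), Nrep (2.65), Sybu (1.89) and Slc22a26 (1.75). The falls in males included the mitochondrial synthetase Lars2 (-2.62), Lrtm1 (-2.60), Depp1 (-2.46), the repressor Snai2 (-1.80) and Synm (-1.60). In females Nrep (2.66), the kinase Nmrk1 (1.67), Sybu (1.47), Fzd7 (1.47) and Nceh1 (1.45) rose. The zinc finger gene Zkscan1 had -0.52 in females, and 0.14 with median centring.

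Skeletal muscle genes such as Ttn and Myh4 stood apart in some pools. In males GH itself was argued against, since the list's median differed by 3.05 between the 2 arrays 30 min after GH, by 2.16 at 90 min and by 2.72 after 2 injections, and a fault of a single array by a further array of the same pool, with a median of 2.97. Both arrays went the same way in females after 2 injections (-3.11 and -2.86, 23 of 25 genes called lower) and in Hypox over sham males (-1.64 and -2.70), so there GH and loss of the pituitary cannot be told apart from what the pools held. Muscle tissue in the RNA may explain the pattern in both male sham pools and 1 male pool 30 min after GH: on 6 arrays of these 3 pools, with none of females after 2 injections, the medians lay between 1.46 and 3.02 in size, at least 1.22 over the 14 members not seen before. The male sham pools were also above female sham pools (1.46 and 2.55), and Hypox females stayed near 0 (0.0067 and 0.0050), where 6 of the 25 genes were well above background in every channel and 0 were in another list.

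Pancreas genes such as Pnlip and Cela3b rose on 1 array of males after 2 injections. The injections were argued against as the cause, since the list's median differed by 3.08 between the 2 arrays, which both carried treated mice. Pancreas tissue in the RNA of 1 pool may explain the pattern: 7 of 7 markers had a log2 ratio over 1 on replicate 2, and 0 on replicate 1.

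Both male sham pools differed in genes that answer to GH. Cish had 0.51 and -3.17 on the 2 arrays of sham males over females and -4.21 and -0.61 on those of Hypox over sham males, which puts it higher in pool 1, and Phlda1 had 1.34 and -1.74, and -4.02 and -1.46. An acute-phase state was argued against by a median pool difference of -0.175 over 21 acute-phase genes on 1 pair of arrays, with 0.374 on the other. A fault of a single array was argued against by a correlation of 0.672 across 270 genes between both estimates of the pool difference, against 0.350 over all genes. A recent pulse of the animals' own GH in pool 1 may explain it: the genes that rose in both sexes 90 min after GH had median pool differences of 0.0588 and 0.0817, beyond 99.92% and 100% of 10000 matched random sets. The random sets were matched on intensity alone. Genes chosen for rising together may also vary together, so these percentiles may be too extreme. On both of its arrays pool 1 was labelled with Alexa 647 and lay on slide 1. Pool 2 was labelled with Alexa 555 and lay on slide 2 on both of its arrays. An effect of labelling or slide beyond the fitted dye effect therefore cannot be told apart from one of the pools. The estimates share it, so their percentiles are not separate evidence.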

How the results depend on the processing

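Fits with slide or scan day as fixed terms, without 5 doubted arrays, without sham arrays or without genes that follow muscle or pancreas, and the Y-linked genes under other scalings, were chosen after seeing the data. Counts are of genes called by limma, and 1 that moved by over 1.5 times is given with its value in the report in brackets. The cause was not tested unless stated.

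Cish in sham males over females had 0.33 without replicate 2 and -2.99 without replicate 1, where its ratio over both arrays was -1.33 and not called. With median centring Zkscan1 from 30 to 90 min in females was 0.14 (-0.52 in the report), and the nuclear receptor genes Nr1i2 and Hnf4a in females at 90 min were 0.18 (-0.49) and 0.26 (-0.36). That centring moved the median of all genes to 0.24 in females at 90 min, to -0.22 in the difference between the sexes there and to 0.24 in the change from 30 min in females, less than these 3 genes moved. Cish at 30 min passed the test without the sham arrays.

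With the scanner's log ratios males at 30 min had 344 genes (657), 150 higher and 194 lower, and females 13 (5). Hypox males over females had 157 (427) and GH-treated males over females 63 (132). The sex difference was 1 gene at 90 min (2) and 178 after 2 injections (518), 70 higher and 108 lower. Females at 90 min had 531 higher and 427 lower, the change from 30 to 90 min 358 higher and 140 lower in males and 28 higher and 6 lower in females. The deposited value table gave 343 (151 higher and 192 lower), 13, 156, 62, 1 and 174 (68 higher and 106 lower) for the same counts. For the shares it gave 523 higher and 424 lower, 362 higher and 141 lower and 28 higher and 6 lower.

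Median centring called fewer genes in most comparisons. Sham males over females had 425 (2300), Hypox males 2998 (9780; 1840 higher and 1158 lower) and Hypox females 1899 (8142). Males had 13 at 30 min (11 higher and 2 lower), 120 at 90 min (1302; 95 higher and 25 lower) and 458 after 2 injections (5058; 324 higher and 134 lower). Females had 2 at 30 min and 81 after 2 injections (2209; 56 higher and 25 lower). In females at 90 min the count was 1058 (830), with 140 of the called genes at the other sign. Hypox males over females had 16 and GH-treated males over females 15. The sex differences were 0, 0 and 0 after GH and 147 after hypophysectomy (1763), and the changes from 30 to 90 min 8 in males (648; 3 higher and 5 lower) and 0 in females (41).

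Without the filter on dim probes the sex difference at 30 min was 1 gene (2), since more genes were tested. Without the dye term females at 90 min had 533, Hypox males over females 227, and the sex differences were 1, 0 and 260. The loop model, which adds indirect paths, gave 4115 for sham males over females, 2616 for Hypox and 914 for GH-treated males over females, and 163 for females at 30 min (75 higher and 88 lower). Its sex differences were 458, 7 and 1411 after GH and 5804 after hypophysectomy, its change from 30 to 90 min in females 130, and males at 30 min had 369 higher and 336 lower. Around the loop the sex difference at 30 min was 0 and that of hypophysectomy 1485.

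With slide as a random block (correlation 0.0975) GH-treated males over females had 225 genes. The sex difference was 1 at 30 min and 929 after 2 injections, and the change from 30 to 90 min in males 1028. With scan day as a block (0.0728) males had 1224 and females 15 at 30 min, Hypox males over females 741 and GH-treated ones 240. The sex differences were 5, 4 and 1225, and the change in males 1101. A block by replicate number gave 2 in females at 30 min and 5 for the sex difference. That block assumes a shift of 1 sign, while arrays of the same number deviated alike in some pairs and oppositely in others: of 55 pairs of comparisons 20 correlated over 0.1, up to 0.871 where both arrays carried the same GH-treated male pool, and 21 under -0.1, down to -0.359.

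A dye balance for each slide gave 401 genes for GH-treated males over females (248 higher and 153 lower) and 1116 for the change from 30 to 90 min in males (534 higher and 582 lower). The other results it left estimable, males after 2 injections (5570) and the change in females (37), stayed within 1.5 times. For these 4 results a dye balance for each scan day is the same fit, so its equal counts are not a further check. Each comparison lay on slides of the same scan day with opposite dyes. For other results it gave 1361 in males at 30 min, and sex differences of 0 at 90 min and 1056 after 2 injections (679 higher and 377 lower). A shift between paired slides gave 1 in females at 30 min, 242 for Hypox and 71 for GH-treated males over females. Its sex differences were 1, 0 and 184 (91 higher and 93 lower) after GH, and its change from 30 to 90 min 3 in females and 291 higher and 295 lower in males.

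With both arrays of a comparison fitted alone, where the spread has fewer degrees of freedom, the counts were 633 for sham males over females, 5708 for Hypox males and 3503 for Hypox females. Males had 0 at 30 min, 416 at 90 min and 1049 after 2 injections, females 109, 5 and 1659. Hypox and GH-treated males over females had 8 and 0. With 4 arrays alone the sex differences were 0, 1 and 0 after GH and 82 after hypophysectomy, and the changes from 30 to 90 min 0 in males and 50 in females.

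Without the doubted arrays, which leaves 1 array in these comparisons, males had 257 at 30 min (239 higher and 18 lower), 74 at 90 min and 2690 after 2 injections (1801 higher and 889 lower). Hypox females had 3370, and GH-treated males over females 14. The sex differences were 48, 0 and 453 after GH and 619 after hypophysectomy, and the changes 40 in males and 6 in females. Without the sham arrays females had 19 at 30 min and 539 at 90 min. The sex differences then were 0, 1 and 321, and the change from 30 to 90 min in females 27. Counts without the genes that follow muscle or pancreas stayed within 1.5 times for all 17 counts.

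Leaving out 1 array at a time, with the lone array assumed to vary like the others, gave 929 to 971 genes for sham males over females, 5051 to 6513 for Hypox males and 3401 to 4983 for Hypox females. Males had 13 to 147 at 30 min, 146 to 329 at 90 min and 1619 to 2867 after 2 injections. Females had 0 to 0, 88 to 501 and 104 to 206. Hypox males over females had 24 to 66 and GH-treated ones 23 to 278. The sex differences were 0 to 13, 0 to 19 and 5 to 131 after GH and 575 to 861 after hypophysectomy. The changes from 30 to 90 min were 25 to 450 in males and 0 to 41 in females. Fewer arrays widen the error.

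For gene lists 79 calls became 8 with an estimated correlation in camera, and were 79 with the scanner's log ratios and with the value table, 85 in the loop model and 87 with the replicate block. Lists with an estimated correlation below the preset one lost calls too, so the fall is not due to correlation between genes alone. Of 627 called values of named genes, 526 passed the test in the same direction with the scanner's log ratios, 527 with the value table, 316 with median centring, 623 in the loop model, 560 without the dye term, 621 with slide and 627 with scan day as a block, 605 with scan day and 541 with paired slides as fixed terms, and 443 without the doubted arrays. With both arrays alone 335 of 530 passed, and with 1 array left out 779 of 1448, with 0 at the other sign. For differences fitted with 4 arrays alone, 19 of 97 passed. Y-linked genes matched the labels on 18 arrays with the scanner's log ratios, 21 with median centring and 18 with the value table. Depth limits genes near background: the red channel of replicate 2 of female Hypox against sham had 24761 spots well above it.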

Other observations

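Some genes of the daily clock changed after hypophysectomy. The clock outputs and repressors Tef (2.53 ± 0.19, adjusted p = 6.4e-07 in males, 1.95 in females) and Nr1d2 (2.16 and 2.07) rose, Cry2 rose in males (1.32) and Nr1d1 in females (1.69), and Clock fell in males (-1.45). Of 17 clock genes, 7 rose and 4 fell in males and 6 rose and 5 fell in females, and camera did not call the list (7 higher and 5 lower adjusted over the list alone, adjusted p = 0.12 and 7 higher and 7 lower adjusted over the list alone, adjusted p = 0.44). The nuclear receptor Nr4a1, an immediate-early gene, rose in Hypox males (2.80) and females (3.73 ± 0.47, adjusted p = 8.9e-05).

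The haem synthesis gene Alas2 of red cells was higher in sham males than in females (2.17 ± 0.21, adjusted p = 2.6e-05), 1 of 3 red cell markers called, and camera did not call that list (adjusted p = 0.30). Of 10 lymphocyte markers, 4 rose in Hypox females, where camera did not call the list (4 higher and 1 lower adjusted over the list alone, adjusted p = 0.25), and 7 in Hypox males. After 2 GH injections in females the female-biased list had 7 genes higher, among them the monooxygenase Fmo2 (1.44), the thioesterase Acot3 (1.61) and Lifr (0.77), and camera did not call it (adjusted p = 0.14). In males after 2 injections it had 4 higher, such as Lifr (1.01), and 8 lower, such as the transcription factor Tox (-1.23; 5 higher and 9 lower adjusted over the list alone, adjusted p = 0.15).

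The tests of restored genes were chosen only after the results were seen. They ask whether genes that hypophysectomy moved in females moved back in males after 2 GH injections, so that no pool is shared. Of 4316 genes lower in Hypox females, 752 rose in males after 2 injections (457 if independent, Fisher's exact odds ratio 2.07, p = 5.6e-51) and 280 fell. Of 3826 genes higher in Hypox females, 856 fell (334 if independent, Fisher's exact odds ratio 4.23, p = 5.1e-180) and 303 rose. GH may restore part of these genes, though genes are not independent of each other and most of them were not called after GH.

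The sex-biased genes of sham mice were followed into Hypox males. Of 1318 genes higher in sham males, 981 fell in Hypox males and 61 rose, and 364 fell in Hypox mice of both sexes. Of 982 genes higher in sham females, 601 rose in Hypox males and 85 fell, and 216 rose in both sexes. The 981 and 601 genes are 74.4% and 61.2% of their sets. The same sham pools are in both comparisons, so sharing was simulated in 20 runs chosen after the results were seen, with fully shared pools and the effects of hypophysectomy shuffled over genes of like intensity. An average of 25.3% (at most 28.3%) of genes higher in males were then called lower, and 30.6% (at most 33.1%) of those higher in females were called higher. With separate pools the averages were 22.0% and 26.1%. The shares in the data lay above those of every run, under a model in which pools differ only by the residual spread. Part of these changes occurred in both sexes, and the shuffled runs do not tell such changes from those of males alone. In 20 other runs, of unchanged genes with shared pools, 86.1% and 87.6% of the sex-biased genes had the opposite sign in Hypox males, against 89.2% and 80.1% in the data. There r was -0.497 against -0.532, so in males signs and r alone do not set the data apart from sharing. In Hypox over sham females r was 0.506 in these runs and 0.078 in the data. Of the genes higher in sham males, 13.8% had a negative ratio there in the runs and 62.4% in the data.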
